A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

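Total RNA of the EC1118 wine yeast was measured on 12 Affymetrix Yeast Genome 2.0 arrays, 3 for the reference culture and 3 for each of the 3 bottle sampling points, with 5 µg of RNA per array and 3' in vitro transcription labelling with biotin, per the labels' protocols. The values used are the deposited log2 probe set summaries, made with RMA (background correction, normalization between arrays and summary of each probe set) per the submitters' processing notes. Its software and version are not given in the sources used here. The raw image files were not used here. No value was rescaled before the main analysis. The median of all probe sets ranged from 6.111 to 7.231 over the arrays and that of the yeast genes tested from 10.05 to 10.15. For arrays no read depth applies, and the 3 arrays per group set the precision.

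The array holds 10928 probe sets for Saccharomyces cerevisiae and Schizosaccharomyces pombe. The annotation paired 5498 with exactly 1 S. cerevisiae gene. The probe set with the highest mean over the 12 arrays was kept for each of the 47 genes with several, which left 5449 genes, and 11 of the 47 had probe sets of opposite sign in a comparison with the reference. In all, 12 symbols were updated through the RefSeq table. The 1746 S. pombe probe sets, 1 with several genes and 3683 unnamed here (213 of them control or reporter probe sets) stayed out of the tests. The 0.95 quantile of the S. pombe probe sets, 4.581 on the log2 scale, served as background. On each array 96.7% to 98.8% of the genes lay above that array's own background, and 5370 genes had a mean above 4.581. A fold change is printed as "at least" where a gene was above background on no array of the lower group. The suffix of 117 genes' probe sets marks sequence shared with other genes.

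Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust settings) in 1 fit of the 4 groups on 12 arrays, with 8 residual degrees of freedom and 3.42 prior degrees of freedom. The 6 pairwise comparisons and a moderated F-test of any difference among the 3 bottle times were drawn from it. Adjusted p is Benjamini-Hochberg within each comparison, and a gene was called at adjusted p under 0.05. Standard errors are limma's moderated ones. Gene lists, 42 in all, were written from textbook knowledge and tested with limma's camera with a preset correlation of 0.01 between genes, with Benjamini-Hochberg over the 42 lists. Camera with an estimated correlation and fry, which tests a list on its own, were run beside it. Some genes stand in more than 1 list. Non-overlap is the share of genes whose 3 arrays of one group all lie above or below the 3 of the other.

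Groups, comparisons, tests, gene lists, the rule for naming genes and all but 3 of the alternatives were chosen before the data were examined. The rule named the 10 genes with the largest change in each direction among those called, not overlapping, above background in the higher group and with a probe set of their own. It also named up to 4 members per list with the largest change. The test was run on simulated data with 200 changed genes among 5449. For day 7 against the reference it recovered 37% of genes changed by a log2 of 1 and 82% of those changed by 2, with 6 false calls among 125, and for day 19 against day 7 42% and 87%, with 6 false calls among 135. Camera called the 1 shifted list of 20 genes and 0 of the other 40 simulated lists. Simulated genes were independent, with the same spread in all groups. The simulation therefore tests neither the preset correlation nor the unequal spread of the real groups.

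Alternatives were median centring, quantile normalization, centring on the S. pombe probe sets, a filter on dim genes, all probe sets, no probe sets with shared sequence, eBayes with trend and robust settings, only the groups compared, array weights, a 2-fold minimum, adjusted p under 0.01, the replicate number as a block, and each array left out in turn. Chosen after seeing the data were leaving out day 7 replicate 1 and day 19 replicate 1, removing each array's trend on coding length, and regrouping the bottle arrays with all 12 arrays in the fit. Coding lengths covered 100% of the genes tested, and 97% were multiples of 3. Correlations across arrays were tested with exact permutation p-values over all 362880 orders. Other splits of the samples were refitted for all 10 splits of 3 against 3, and for 100 drawn groupings otherwise. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.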

Results

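Transcript levels were measured on 12 single-colour Affymetrix arrays of total RNA from EC1118, a commercial wine yeast strain of Saccharomyces cerevisiae. The reference group was an unstressed culture in YPD, a rich glucose medium, growing exponentially at 28 °C to an optical density of 1.0. The other 3 groups came from the second fermentation, the step in which base wine is refermented in closed bottles to give sparkling wine. Yeast adapted to ethanol beforehand and 20 g/L of sucrose had been added to the wine, and 350 mL bottles stood at 16 °C for about 40 days. Samples were taken at day 7, day 15 and day 19, when ethanol had risen by 0.26%, 0.89% and 1.27%, per the labels. Each group holds 3 arrays, which the labels call biological replicates, and this number limits the precision of every value. For the bottles the labels speak of independent tirage assays. For the reference they do not say whether the replicates were separate cultures, so the spread between its arrays may be technical. The p-values use a spread per gene pooled over all groups, so those against the reference may not cover differences between reference cultures.

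The arrays of the reference lay closer together than those of the bottles. The correlation between replicates across genes ranged from 0.987 to 0.997 in the reference, 0.892 to 0.966 at day 7, 0.917 to 0.980 at day 15 and 0.817 to 0.939 at day 19. The median standard deviation of a gene was 0.118 on the log2 scale in the reference, 0.321 at day 7, 0.295 at day 15 and 0.428 at day 19. The first principal component held 58.8% of the variance and separated the reference from the bottles. The second held 15.7% and set day 7 replicate 1 and day 19 replicate 1 apart from the other 7 bottle arrays.

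**Figure D1:**
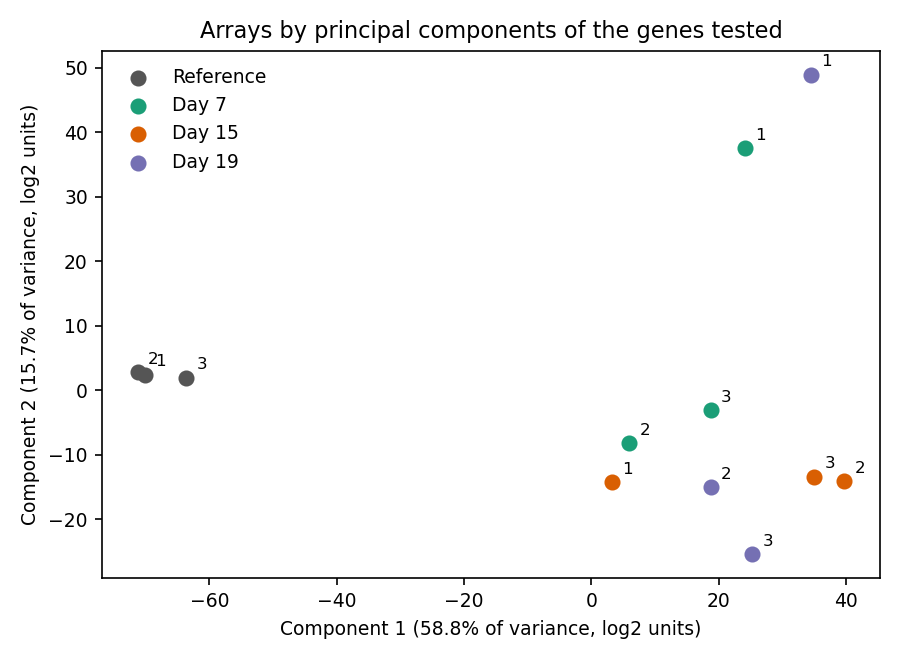
Each point is 1 array, coloured by group and numbered by replicate, on the first and second principal components of the 5449 genes tested (58.8% and 15.7% of the variance, log2 units). The 3 reference arrays lie on the left, and day 7 replicate 1 and day 19 replicate 1 lie above the other bottle arrays.

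Day 7 was set against the reference to ask how cells early in the second fermentation differ from cells growing without stress. The groups differ in medium, temperature, ethanol and growth phase at once. Genes of respiration, of the general stress response and of growth on carbon sources other than sugar were higher in the bottles, and genes of ribosome production, translation and the cell cycle were lower. Changes are log2 differences of the group means ± standard error, with 3 arrays in each group. STL1, which encodes a glycerol symporter of the plasma membrane, rose by 7.21 ± 0.748 (adjusted p = 6.92e-05), with 1 of its 3 reference arrays above background. The stress genes DDR2 and HSP12 rose by 6.46 ± 0.397 and 5.51 ± 0.68. CYB2, the mitochondrial lactate dehydrogenase, rose by 5.75 ± 0.739, PUT4, the proline permease, by 5.38 ± 0.672 and the phosphatase gene PHM8 by 5.39 ± 0.592. Among the genes that fell, YAR068W changed by -5.88 ± 0.214 (adjusted p = 4.71e-08), AAC3, an ADP/ATP carrier known from anaerobic growth, by -4.51 ± 0.585, the acid phosphatase gene PHO3 by -3.55 ± 0.452 and the S-phase cyclin gene CLB6 by -3.37 ± 0.403.

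At day 7, limma called 1076 genes higher and 931 lower of the 5449 tested, and 806 and 615 of them changed by at least 2-fold. The arrays of the groups did not overlap for 63.8% of genes, where chance gives 10%. Probe sets of ribosomal RNA averaged 12.20 ± 1.02 (SD, n = 3) at day 7 and 6.40 ± 1.34 in the reference, and genes called lower had a median coding length of 1380 bases against 1104 for genes called higher. Without reference replicate 1, 2 or 3 the number of lower genes was 554, 535 and 553, and with array weights 1786 genes were higher and 1697 lower.

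**Figure D2:**
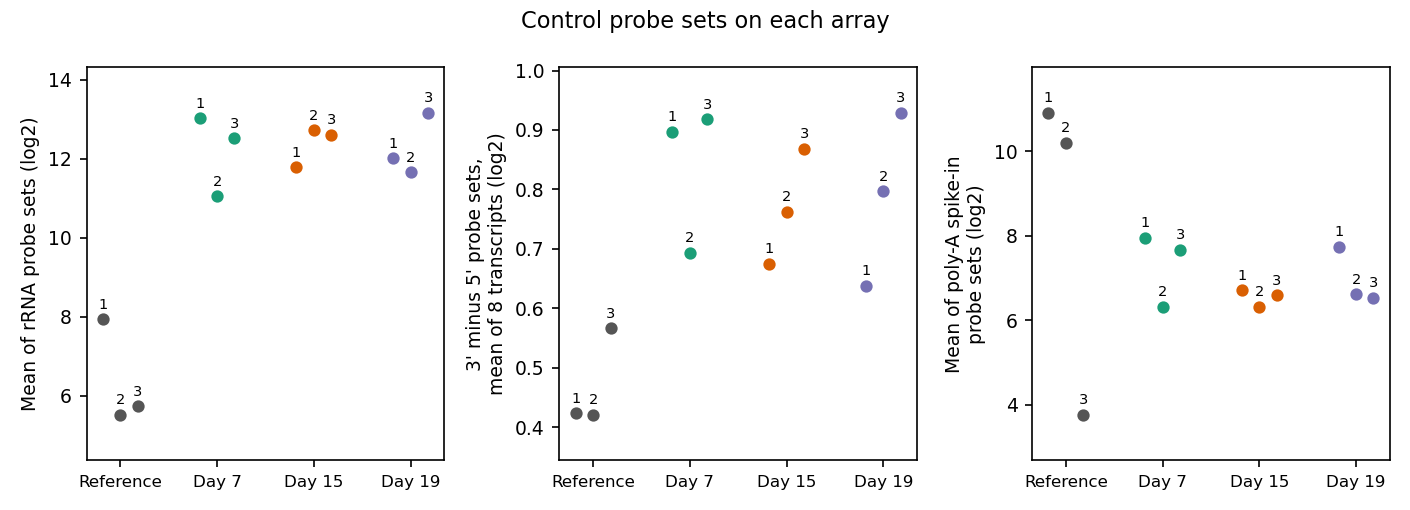
Mean log2 signal of 17 ribosomal RNA probe sets, 3' minus 5' difference of 8 transcripts and mean log2 signal of 12 poly-A spike probe sets on each of the 12 arrays, by group. The poly-A spikes ranged from 3.758 to 10.91 in the reference and from 6.318 to 7.948 in the bottles. Every reference array lay outside the bottle range, replicates 1 and 2 above it and replicate 3 below it.

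Respiration and the use of carbon sources other than sugar stood out at day 7. Of the genes of the respiratory chain and ATP synthase, 39 of 40 rose and 1 did not pass (40 rose adjusted over the list alone); the NADH dehydrogenase gene NDI1 rose by 2.41 ± 0.305 and QCR10, of the cytochrome bc1 complex, by 2.25 ± 0.193. Of the tricarboxylic acid cycle genes, 11 of 16 rose and 5 did not pass (12 rose adjusted over the list alone), among them SDH2 with 2.19 ± 0.231 and SDH4 with 2.07 ± 0.194, both subunits of succinate dehydrogenase. In the glyoxylate cycle and gluconeogenesis list, 12 of 18 rose and 6 did not pass (14 rose adjusted over the list alone). FBP1 and PCK1, enzymes of gluconeogenesis, rose by 4.89 ± 1.22 and 4.77 ± 1.22, the malate synthase gene MLS1 by 4.65 ± 1.01 and CAT8, a regulator of gluconeogenic genes, by 4.45 ± 0.616. Among genes of fatty acid beta-oxidation and the peroxisome, 16 of 32 rose, 1 fell and 15 did not pass (17 and 1 adjusted over the list alone), and POT1 and CRC1, for a thiolase and a carnitine carrier, rose by 5.10 ± 0.849 and 5.03 ± 0.489. Camera's adjusted p for these 4 lists was 1.33e-19, 2.91e-07, 1.47e-05 and 2.66e-05, and for each of them adjusted p = 0.408 with an estimated correlation. Of the glycolysis genes, 4 of 16 rose, 2 fell and 10 did not pass (4 and 2 adjusted over the list alone), with HXK1 and GLK1, which phosphorylate glucose, at 1.82 ± 0.22 and 1.81 ± 0.193 (list adjusted p = 0.412). In ethanol and acetate metabolism, 7 of 16 rose, 1 fell and 8 did not pass (7 and 1 adjusted over the list alone), with ALD4, an aldehyde dehydrogenase, at 2.58 ± 0.454 (list adjusted p = 0.0747).

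Most storage carbohydrate genes and part of the genes of sugar uptake and use were also higher at day 7. Of hexose transporters and sensors, 10 of 23 rose and 13 did not pass (10 rose adjusted over the list alone), with HXT8 at 2.52 ± 0.502 (1 of 3 reference arrays above background). In the sucrose and maltose list, 4 of 10 rose and 6 did not pass (5 rose adjusted over the list alone), with the invertase gene SUC2 at 2.98 ± 0.335 and the isomaltase gene IMA1 at 2.48 ± 0.583. Of the trehalose and glycogen genes, 15 of 21 rose, 1 fell and 5 did not pass (17 and 1 adjusted over the list alone). GPH1, the glycogen phosphorylase, rose by 2.94 ± 0.383, the trehalase genes ATH1 and NTH2 by 2.58 ± 0.466 and 2.52 ± 0.335, and GAC1, a phosphatase subunit that acts on glycogen synthase, by 4.19 ± 0.489. Camera's adjusted p was 0.00897, 0.0197 and 3.96e-06 for the 3 lists, and for each of them adjusted p = 0.408 with an estimated correlation. The hexose transporter call was lost (adjusted p = 0.0625) over the 19 members with probe sets of their own, and quantile normalization ended the sucrose and maltose call (median 1.16 in place of 1.79, adjusted p = 0.116). The glycerol and osmotic stress list went both ways: 5 of 14 rose, 3 fell and 6 did not pass (5 and 3 adjusted over the list alone), with the glycerol-3-phosphate dehydrogenase genes GUT2 at 3.76 ± 0.373 and GPD2 at -3.04 ± 0.516 (list adjusted p = 0.128).

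Many stress genes were higher at day 7. Of the general stress genes, 51 of 56 rose and 5 did not pass (52 rose adjusted over the list alone), with NQM1 at 5.37 ± 0.495 and SIP18 at 5.36 ± 1.13. Among stationary-phase and quiescence markers, 16 of 24 rose and 8 did not pass (17 rose adjusted over the list alone), with the cell wall gene SPI1 at 3.71 ± 0.256. In the oxidative stress list, 18 of 38 rose, 2 fell and 18 did not pass (19 and 3 adjusted over the list alone), with CTT1, the cytosolic catalase, at 4.36 ± 0.428, OYE3 at 4.86 ± 0.684 and the sulfiredoxin gene SRX1 at 2.62 ± 0.242. For these 3 lists camera's adjusted p was 3.53e-18, 2.29e-07 and 0.000704, and adjusted p = 0.408 with an estimated correlation. Of heat shock proteins and chaperones, 11 of 39 rose, 3 fell and 25 did not pass (11 and 3 adjusted over the list alone), with HSP26 at 2.79 ± 0.398; its adjusted p was 0.0231, and adjusted p = 0.552 with an estimated correlation. That call, with a median of 0.40, was lost without day 7 replicate 2 (median 0.25, adjusted p = 0.16), and the median was 0.81 without day 7 replicate 1.

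Genes of self-degradation and of cell differentiation rose in part at day 7. Of the autophagy genes, 16 of 36 rose and 20 did not pass (19 rose adjusted over the list alone), with ATG8, the ubiquitin-like protein of the autophagosome membrane, at 2.63 ± 0.2 and ATG39, a receptor for the breakdown of the nuclear envelope, at 4.43 ± 0.751. Among vacuolar proteases and hydrolases, 8 of 16 rose, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone), with AMS1 at 3.11 ± 0.197 and PRB1, vacuolar protease B, at 2.39 ± 0.217. The proteasome list had 11 of 36 members that rose and 25 that did not pass (9 rose adjusted over the list alone), with RPN4, the regulator of proteasome genes, at 1.63 ± 0.301. Of the meiosis and sporulation genes, 22 of 51 rose and 29 did not pass (22 rose adjusted over the list alone), with RIM4 at 4.81 ± 0.625 and NDT80, a regulator of middle meiosis, at 2.81 ± 0.421. Among mating genes, 9 of 26 rose, 1 fell and 16 did not pass (10 and 1 adjusted over the list alone), with the receptor gene STE3 at 2.08 ± 0.337. AGA2, an agglutinin subunit not above background in the reference, was at least 5.09-fold higher. Camera's adjusted p for the 5 lists was 3.03e-06, 0.00676, 0.000101, 4.59e-05 and 0.00531. With an estimated correlation they were adjusted p = 0.408, 0.408, 0.521, 0.408 and 0.47. Quantile normalization ended the meiosis and mating calls: the medians went from 1.07 to 0.28 and from 0.89 to 0.16 (adjusted p = 0.0694 and 0.355).

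Genes of growth were lower at day 7. Of the ribosome biogenesis genes, 64 of 100 fell and 36 did not pass (80 fell adjusted over the list alone), with the helicase gene DBP2 at -2.62 ± 0.579 and KRE33, an RNA acetyltransferase, at -2.01 ± 0.331. Of RNA polymerase I and III subunits, 15 of 19 fell and 4 did not pass (15 fell adjusted over the list alone), with RPA43 at -2.26 ± 0.387. Among cytosolic translation factors, 24 of 35 fell and 11 did not pass (25 fell adjusted over the list alone), with TIF4631, which encodes eIF4G, at -1.74 ± 0.371 and PRT1, of eIF3, at -1.55 ± 0.245. Of cytosolic ribosomal proteins, 24 of 127 fell and 103 did not pass (6 fell adjusted over the list alone), with a median of -0.40 and RPL6B at -1.10 ± 0.249. That count is close to the share among all genes, where 931 of 5449 were called lower. Cell cycle genes had 14 of 35 members that fell and 21 that did not pass (14 fell adjusted over the list alone), with the cyclin genes CLB1 at -3.31 ± 0.625 and CLN2 at -2.54 ± 0.643. In DNA replication and histones, 15 of 42 fell and 27 did not pass (15 fell adjusted over the list alone), with RNR1, a subunit of ribonucleotide reductase, at -3.01 ± 0.513. Camera's adjusted p for these 6 lists was 6.41e-15, 1.07e-05, 1.31e-07, 5.11e-08, 5.13e-05 and 0.00198. With an estimated correlation it was adjusted p = 0.521 for ribosomal proteins and 0.408 for the other 5. Few mitochondrial ribosomal proteins passed: 12 of 70 rose and 58 did not pass (7 rose adjusted over the list alone), where 1076 of all 5449 genes were called higher. The list median was 0.28 (adjusted p = 0.00676 by camera's preset test, and adjusted p = 0.67 with an estimated correlation). Without day 7 replicate 2 the adjusted p of the preset test was 0.0594.

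Nitrogen, sulfur and iron genes went both ways at day 7. Of the genes under nitrogen catabolite repression, 17 of 37 rose, 4 fell and 16 did not pass (18 and 5 adjusted over the list alone), with DAL80, a repressor of that regulon, at 4.11 ± 0.659 (1 of 3 reference arrays above background) and the proline oxidase gene PUT1 at 2.80 ± 0.314. Amino acid biosynthesis had 8 of 64 members that rose, 19 that fell and 37 that did not pass (8 and 23 adjusted over the list alone), with GDH3, a glutamate dehydrogenase, at 4.03 ± 0.861 and SER2, of serine synthesis, at -2.61 ± 0.386. Their adjusted p values were 0.00477 upward and 0.00676 downward, and adjusted p = 0.437 and 0.521 with an estimated correlation. The nitrogen median of 1.08 was 0.72 without day 7 replicate 1. Of sulfur assimilation and methionine genes, 10 of 33 rose, 3 fell and 20 did not pass (10 and 3 adjusted over the list alone), with MET2 at 3.96 ± 0.376 and STR3 at 3.09 ± 0.366 (list adjusted p = 0.0727). In the iron regulon, 13 of 31 rose, 4 fell and 14 did not pass (13 and 4 adjusted over the list alone), with HMX1, a heme oxygenase, at 3.47 ± 0.605 (list adjusted p = 0.0784).

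Few ergosterol and seripauperin genes passed the test at day 7, and the fatty acid synthesis and hypoxic lists went both ways. Of the ergosterol genes, 3 of 27 fell and 24 did not pass (2 fell adjusted over the list alone), with ECM22, a regulator of sterol genes, at -1.74 ± 0.315 and ERG24 at -1.27 ± 0.258. Fatty acid synthesis and desaturation had 2 of 16 members that rose, 7 that fell and 7 that did not pass (2 and 7 adjusted over the list alone), with the acyl-CoA synthetase genes FAA1 at 2.90 ± 0.283 and FAA4 at -2.99 ± 0.218. Camera's adjusted p was 0.0297 and 0.0196, and adjusted p = 0.678 and 0.408 with an estimated correlation. The ergosterol call, with a median of -0.48, was lost without day 7 replicate 1 (median -0.01, adjusted p = 0.463) and with quantile normalization (median -0.52, adjusted p = 0.0627). Without day 7 replicate 3 the median was -0.85. In the hypoxic and anaerobic list, 4 of 23 rose, 5 fell and 14 did not pass (4 and 6 adjusted over the list alone); the median was 0.32 while its mean was -0.04 and its test pointed downward (adjusted p = 0.627). HEM13, a heme synthesis gene known to be repressed by oxygen, stood at -2.92 ± 0.485. Of the seripauperin genes, a family of cell wall mannoproteins known from anaerobic and cold growth, 1 of 13 rose and 12 did not pass (1 rose adjusted over the list alone), with PAU21 at least 3.86-fold higher, a call that quantile normalization ended (list adjusted p = 0.416).

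Day 15 against the reference asks the same of cells in the middle of the sampled period. Respiratory and stress genes were again higher and genes of ribosome production lower, and most of the seripauperin genes were higher as well. DDR2 rose by 6.18 ± 0.397 (adjusted p = 5.26e-06), CYB2 by 6.37 ± 0.739, NCA3, which is linked to mitochondrial function, by 5.56 ± 0.211, SIP18 by 6.13 ± 1.13 and the thiolase gene POT1 by 6.17 ± 0.849. YAR068W changed by -5.20 ± 0.214, the amino acid permease gene DIP5 by -4.84 ± 1.02, GPD2, of glycerol synthesis, by -3.49 ± 0.516 and SER2 by -3.55 ± 0.386. limma called 1164 genes higher and 1283 lower, 910 and 871 of them by at least 2-fold, and the groups did not overlap for 70.8% of genes, where chance gives 10%. Probe sets of ribosomal RNA averaged 12.37 ± 0.515 (SD, n = 3), and genes called lower had a median coding length of 1440 bases against 1107 for genes called higher. Without day 15 replicate 2 the number of lower genes was 826, and with array weights 2115 genes were higher and 2322 lower.

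Among the lists at day 15, the respiratory chain had 39 of 40 members that rose and 1 that did not pass (39 rose adjusted over the list alone), with CYT1, of the cytochrome bc1 complex, at 2.49 ± 0.225. General stress genes had 49 of 56 members that rose, 0 that fell and 7 that did not pass (50 and 1 adjusted over the list alone), with MOH1 at 5.06 ± 0.591, and trehalose and glycogen genes had 17 of 21 members that rose, 1 that fell and 3 that did not pass (17 and 1 adjusted over the list alone). Of meiosis and sporulation genes, 28 of 51 rose, 1 fell and 22 did not pass (30 and 1 adjusted over the list alone), with SPO20 at 3.65 ± 0.452 (2 of 3 reference arrays above background), and of mating genes 15 of 26 rose, 1 fell and 10 did not pass (16 and 1 adjusted over the list alone). Ribosome biogenesis had 80 of 100 members that fell and 20 that did not pass (84 fell adjusted over the list alone), with UTP4 at -2.81 ± 0.486 and UTP8 at -2.69 ± 0.407, both of the complex that processes pre-ribosomal RNA. Their adjusted p values were 2.61e-18, 3.02e-17, 2.03e-06, 6.96e-08, 0.000102 and 3.88e-15, and for each of the 6 lists adjusted p = 0.401 with an estimated correlation. Of the proteasome genes, 1 of 36 rose, 1 fell and 34 did not pass (1 and 0 adjusted over the list alone) (adjusted p = 0.837), and of the ergosterol genes 3 of 27 rose, 1 fell and 23 did not pass (2 and 1 adjusted over the list alone), with ERG9, squalene synthase, at 1.29 ± 0.349 (adjusted p = 0.253). Of the 13 seripauperin genes, 9 of 13 rose and 4 did not pass (11 rose adjusted over the list alone), with PAU5 at 4.24 ± 1.05 (adjusted p = 0.000742, and adjusted p = 0.452 with an estimated correlation). Over the 3 seripauperin genes with probe sets of their own the list call was lost (median 1.84, adjusted p = 0.4).

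**Figure D3:**
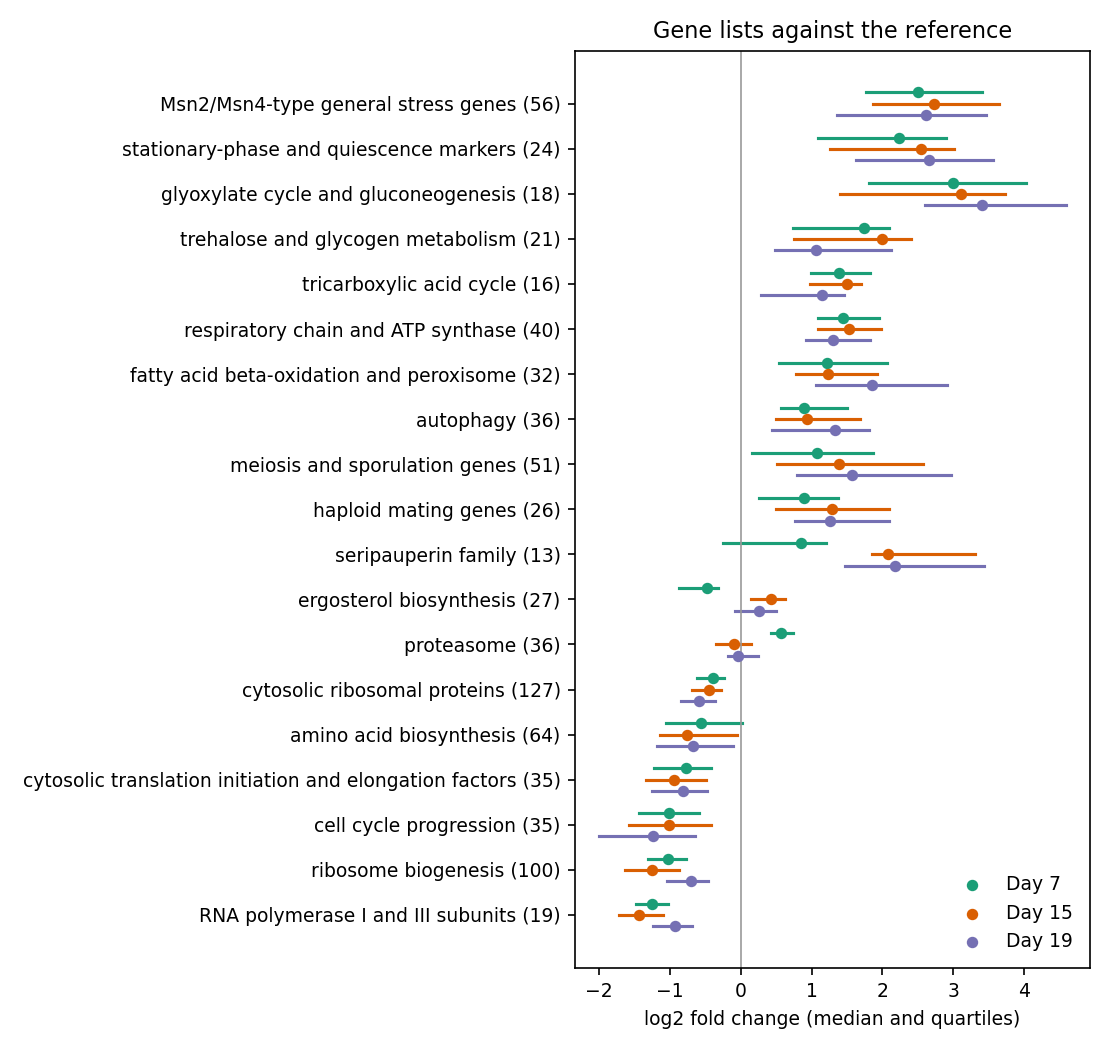
Points are medians and bars quartiles of the log2 fold change of the members of 19 gene lists (number measured in parentheses) at day 7, day 15 and day 19 against the reference. General stress genes have medians of 2.50, 2.73 and 2.61, and ribosome biogenesis genes -1.03, -1.25 and -0.70.

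Day 19 against the reference covers the latest sampling point. Genes of fatty acid breakdown, sporulation and stress were among those highest above the reference, and cyclin and cell division genes among those lowest. SIP18 rose by 7.59 ± 1.13 (adjusted p = 0.000507), DDR2 by 6.57 ± 0.397, the carnitine carrier gene CRC1 by 6.21 ± 0.489 and ADY2, an acetate transporter gene, by 6.14 ± 1.21. SHH3 rose by 6.64 ± 1.1 with 1 of its 3 reference arrays above background, and PEX18, of peroxisomal import, which was not above background in the reference, was at least 40.3-fold higher. CLB1 and CLB2, cyclin genes of mitosis, changed by -3.93 ± 0.625 and -3.69 ± 0.968, the chitin synthase gene CHS2 by -3.66 ± 0.746, UTR2, of the cell wall, by -3.75 ± 0.719 and TOS6 by -4.94 ± 0.646. limma called 1238 genes higher and 1134 lower, 928 and 742 of them by at least 2-fold, and the groups did not overlap for 59.5% of genes, where chance gives 10%. Probe sets of ribosomal RNA averaged 12.28 ± 0.791 (SD, n = 3), and genes called lower had a median coding length of 1455 bases against 1083 for genes called higher. Without reference replicate 1 or 2 the number of lower genes was 729 and 711.

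Among the lists at day 19, beta-oxidation and peroxisome genes had 27 of 32 members that rose, 1 that fell and 4 that did not pass (27 and 1 adjusted over the list alone), with the peroxisomal catalase gene CTA1 at 4.97 ± 0.916. The glyoxylate cycle and gluconeogenesis had 15 of 18 members that rose and 3 that did not pass (15 rose adjusted over the list alone), with FBP1 at 5.55 ± 1.22. Of the meiosis and sporulation genes, 35 of 51 rose and 16 did not pass (36 rose adjusted over the list alone), with SPS100, of the spore wall, at 5.57 ± 0.994, and of quiescence markers 18 of 24 rose and 6 did not pass (22 rose adjusted over the list alone). Translation factors had 24 of 35 members that fell and 11 that did not pass (24 fell adjusted over the list alone) and cell cycle genes had 0 of 35 members that rose, 22 that fell and 13 that did not pass (1 and 24 adjusted over the list alone). For these 6 lists camera's adjusted p was 6.31e-08, 9.91e-07, 5.87e-10, 1.06e-08, 1.08e-07 and 2.55e-06, and adjusted p = 0.414 with an estimated correlation. Ribosomal proteins had 64 of 127 members that fell and 63 that did not pass (69 fell adjusted over the list alone), with RPL9A at -1.79 ± 0.429, and -1.18 without day 19 replicate 3 (list adjusted p = 9.16e-12, and adjusted p = 0.527 with an estimated correlation). Of the ribosome biogenesis genes, 1 of 100 rose, 36 fell and 63 did not pass (1 and 34 adjusted over the list alone) (adjusted p = 2.37e-07, and adjusted p = 0.559 with an estimated correlation). The seripauperin genes had 9 of 13 members that rose and 4 that did not pass (11 rose adjusted over the list alone) (adjusted p = 0.00171, and adjusted p = 0.527 with an estimated correlation), a call lost over the 3 with probe sets of their own (median 1.16, adjusted p = 0.598), and the median of all was 2.18, or 1.43 without day 19 replicate 3.

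Over the 3 comparisons with the reference, 816 genes were called higher and 670 lower at every bottle time. In each of 20 simulations of all 12 arrays without any change, the bottle groups shared 0 genes. Genes were drawn independently with the same spread in all groups, so few calls could arise and the simulation does not test the shared reference. Independent lists of the same sizes would share 52.2 and 45.6 genes. The 3 reference arrays were too few to split, so part of the excess may come from the shared reference. FET3, a multicopper oxidase of iron uptake, was the 1 gene called in opposite directions, lower at day 7 (-1.50 ± 0.474) and higher at day 19 (1.40 ± 0.474); it was picked out after its values were seen. Without reference replicate 1, 2 or 3 the number lower at every time was 372, 358 and 392, and with array weights 1310 genes were higher and 1153 lower. Camera called 27, 26 and 22 of the 42 lists at day 7, day 15 and day 19, and 0 of these calls held with an estimated correlation, while fry, which tests each list on its own, called 31, 30 and 26.

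Day 15 against day 7 asks what changed within the bottles as fermentation went on. No single gene passed the test, while list medians moved in genes of the seripauperin family, sterol synthesis and the proteasome. limma called 0 genes (572 at an unadjusted p under 0.05, with fry calling 0 of 42 lists), and the groups did not overlap for 15.3% of genes, where chance gives 10%. Camera's preset test placed the seripauperin list higher with a median of 1.72 (adjusted p = 4.79e-10). Of its members, 0 of 13 rose over all genes tested and 9 adjusted over the list alone, with PAU5 at 2.92 ± 1.05 (adjusted p = 0.424). Only 3 of the 13 have probe sets of their own, so the members may not be independent measures. Over those 3 the median was 2.12 (adjusted p = 0.00917 by the same test). Ergosterol genes had a median of 0.92 (adjusted p = 4.77e-12), with 0 of 27 members passing by either adjustment and HMG1, an enzyme of the mevalonate pathway, at 1.79 ± 0.618 (adjusted p = 0.424). Proteasome genes had a median of -0.66 (adjusted p = 6.57e-15), with 0 of 36 members passing and PRE3 at -1.09 ± 0.35. For these 3 lists, adjusted p = 0.704 with an estimated correlation. Day 7 replicate 1, which stood apart from the other bottle arrays, had a mean of 10.93 over the ergosterol genes against 12.03 and 12.32 on the other day 7 arrays, and without it the ergosterol median was 0.48. Without day 15 replicate 1, 27 genes were higher and 80 lower, without day 19 replicate 1 the counts were 5 and 1, without day 7 replicate 3 they were 1 and 0, and with array weights 594 and 880. Without day 7 replicate 1 and day 19 replicate 1 together, chosen after seeing the data, 2 genes were higher and 1 was lower.

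Day 19 against day 15 compares the last sampling points. Here too no gene passed the test, while list medians moved in glyoxylate and gluconeogenesis, ribosome biogenesis, chaperones and storage carbohydrates. limma called 0 genes (600 at an unadjusted p under 0.05, with fry calling 0 of 42 lists), and the groups did not overlap for 12.7% of genes, where chance gives 10%. By camera's preset test ribosome biogenesis was higher at day 19 with a median of 0.52 (adjusted p = 3.04e-13), with MAK16 at 1.44 ± 0.39 (adjusted p = 0.26). Chaperones were lower by the same test with a median of -0.60 (adjusted p = 4.27e-08), with the Hsp90 cochaperone gene AHA1 at -1.63 ± 0.542. Trehalose and glycogen genes were lower with a median of -0.61 (adjusted p = 6.45e-06), with the phosphoglucomutase gene PGM2 at -1.05 ± 0.39. Mitochondrial ribosomal proteins had a median of -0.29 (adjusted p = 4.48e-11), and -0.19 without day 15 replicate 3. For these 4 lists, adjusted p = 0.821 with an estimated correlation; 0 of their members passed over all genes tested and 1 trehalose and glycogen gene and 1 mitochondrial ribosomal gene fell adjusted over the list alone. The chaperone median was -0.33 without day 19 replicate 2 and -1.18 without day 19 replicate 3, and that of trehalose and glycogen -0.39 without day 15 replicate 2. The glyoxylate cycle and gluconeogenesis had a higher median, 0.80 (adjusted p = 0.0439, and adjusted p = 0.868 with an estimated correlation), with 0 of 18 members passing by either adjustment. That call was lost with centring on the S. pombe probe sets (adjusted p = 0.0593) and with shared-sequence probe sets left out of all genes (adjusted p = 0.0533). It was also lost without day 7 replicate 1 or 3 (adjusted p = 0.0551 and 0.0552), where the median stayed at 0.80, and without day 15 replicate 1 (median 0.525, adjusted p = 0.717). Without day 19 replicate 1 the test pointed the other way with a median of 0.0587; without day 19 replicate 2 the median was 1.28. On day 19 replicate 1 the mean over the seripauperin genes was 9.19 against 11.67 and 12.07 on the other day 19 arrays. Without that array 33 genes were higher and 16 lower, without day 19 replicate 3 the counts were 0 and 1, and with array weights 514 and 290. Without it and day 7 replicate 1 together, chosen after seeing the data, 173 genes were higher and 88 lower.

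Day 19 against day 7 spans the whole sampled period, and it was the bottle comparison with single genes past the test. These calls rest on a spread pooled with the reference arrays. The median standard deviation of a gene was 0.118 in the reference, 0.321 at day 7 and 0.428 at day 19. The standard errors given here may therefore be too small. Fitted on the arrays of days 7 and 19 alone, 0 genes were called. IZH4, a membrane protein gene linked to zinc and sterol metabolism, rose by 4.12 ± 0.584 (adjusted p = 0.022), FET3, of iron uptake, by 2.90 ± 0.474 (adjusted p = 0.0441) and RNR3, a subunit of ribonucleotide reductase, by 2.07 ± 0.258 (adjusted p = 0.0139). FAA4, an acyl-CoA synthetase gene, rose by 1.95 ± 0.218 (adjusted p = 0.0092), PLB2, a phospholipase B gene, by 1.80 ± 0.235 (adjusted p = 0.0143), MGA2, a regulator of the fatty acid desaturase gene, by 1.76 ± 0.253 (adjusted p = 0.022) and GAS2, a glucan transferase gene of the spore wall, by 1.28 ± 0.202 (adjusted p = 0.041). YCH1, a phosphatase gene, fell: its change was -1.73 ± 0.277 (adjusted p = 0.0418). All 3 day 19 arrays lay beyond all 3 day 7 arrays for each of the 8 genes. This adds no support, because the genes were picked by their test on these same arrays. FAA4 stood at 10.67 ± 0.352 (SD, n = 3) at day 7, 11.52 ± 0.0581 at day 15 and 12.62 ± 0.284 at day 19, and at 13.66 ± 0.0433 in the reference. RNR3 stood at 9.05 ± 0.0883 at day 7, 9.76 ± 0.514 at day 15 and 11.12 ± 0.123 at day 19, and at 8.90 ± 0.295 in the reference.

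**Figure D4:**
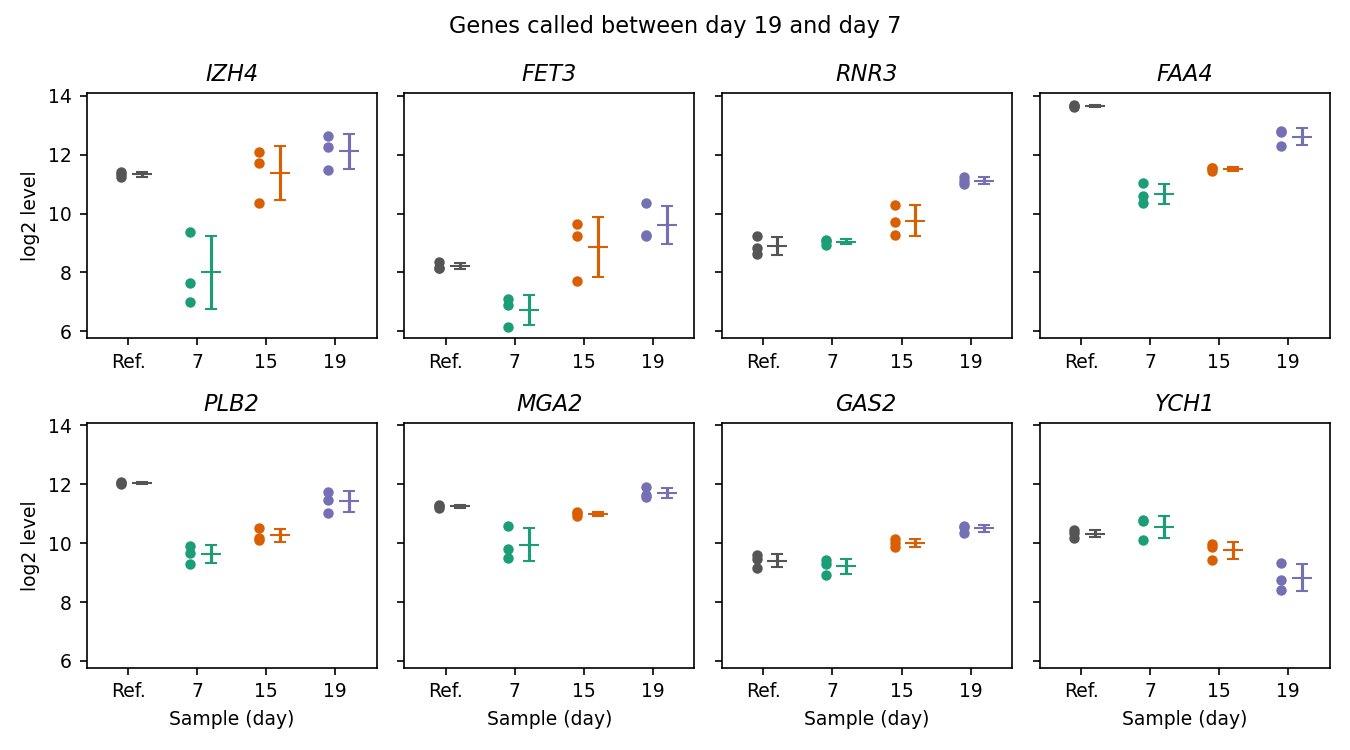
Log2 level of the 8 genes called between day 19 and day 7 on each array (points) with the group mean ± SD (bars), in the reference and at day 7, 15 and 19. IZH4 has means of 11.33 in the reference and 12.12 at day 19.

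Between day 19 and day 7 limma called 7 genes higher and 1 lower (675 at an unadjusted p under 0.05), and the groups did not overlap for 12% of genes, where chance gives 10%. The F-test of any difference among the 3 bottle times called FAA4 (adjusted p = 0.0366) and RNR3 (adjusted p = 0.0482), with 687 genes at an unadjusted p under 0.05. Fitted on the bottle arrays alone, without the reference, the F-test called 0 genes. Of the lists, meiosis and sporulation was higher by camera's preset test with a median of 0.64 (adjusted p = 1.82e-09); 1 of 51 members, GAS2, rose and 50 did not pass (5 rose adjusted over the list alone). The seripauperin list had a median of 1.61 (adjusted p = 2.07e-07), with 0 of 13 rising over all genes tested and 7 adjusted over the list alone, ergosterol 0.78 (adjusted p = 2.07e-07) and hypoxic genes 0.83 (adjusted p = 0.000117). Over the 3 seripauperin genes with probe sets of their own the median was 1.44 (adjusted p = 0.0454 by the same test). Proteasome genes were lower with a median of -0.62 (adjusted p = 4.74e-13) and glycerol genes with -0.65 (adjusted p = 0.000351), and of the ergosterol, hypoxic, proteasome and glycerol members 0 passed by either adjustment. For these 6 lists, adjusted p = 0.51 with an estimated correlation, and fry called 0 of 42. Single arrays moved several of these medians. Without day 7 replicate 1 they were 0.35 for ergosterol and 0.41 for hypoxic genes, and without day 19 replicate 1 they were 1.26, 1.46 and, for seripauperin genes, 2.48. Hypoxic genes came to 0.47 without day 19 replicate 2, and without day 19 replicate 3 seripauperin genes came to 1.02 and glycerol genes to -0.43.

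The counts between day 19 and day 7 moved with single arrays. Without day 19 replicate 1, 235 genes were higher and 158 lower, and without day 7 replicate 1, 22 and 12. Without day 15 replicate 1 they were 9 and 2, and without day 15 replicate 3 they were 6 and 0. Without any 1 reference array, or day 7 replicate 3, or day 15 replicate 2, 3 genes were higher and 0 lower. Without day 7 replicate 2 or day 19 replicate 2 the counts were 2 and 0, and without day 19 replicate 3 they were 0 and 0. The F-test called 197 genes without day 19 replicate 1, 59 without day 15 replicate 1, 1 without day 7 replicate 1 or day 15 replicate 2, 2 without day 7 replicate 3, and 0 without any 1 of the other 7 arrays. Fitted on the 6 arrays alone, 0 genes were called, and with array weights 251 were higher and 193 lower. Without day 7 replicate 1 and day 19 replicate 1 together, chosen after seeing the data, 314 genes were higher and 220 lower, among them all 8 of the genes above. That fit uses arrays from which the 8 genes were picked, so it is no separate support for them.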

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

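Of the tests in this part, those of fragmented RNA, of a labelling batch and of array quality were chosen after the result was seen, and so were the removal of the length trend, the fits without 2 arrays and the splits with all 12 arrays. The rest were set beforehand. The test of array quality as first written asked for at least 1 of 4 measures. That was met by 1 measure, and since chance gives as many in a share of 0.204, it is left as deciding nothing.

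Several results stood out because groups that were sampled at different times differed by test. Between day 19 and day 7 the log2 differences were 4.12 for IZH4, 2.90 for FET3, 2.07 for RNR3, 1.95 for FAA4, 1.80 for PLB2, 1.76 for MGA2, 1.28 for GAS2 and -1.73 for YCH1. The F-test among the bottle times gave adjusted p = 0.0366 for FAA4 and 0.0482 for RNR3. Another result came from probe sets outside the genes tested: those of ribosomal RNA were higher in the bottles by 5.88 on the log2 scale.

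The bottle arrays had higher ribosomal RNA signal and a larger 3' minus 5' difference than the reference (0.798 ± 0.111 against 0.470 ± 0.0834, SD, exact permutation p = 0.00455 for both), and genes called lower were longer. The 3' minus 5' difference is a mean over 8 transcripts that were not uniform. Bottle minus reference was -0.326 for RIP1 and -0.0396 for TDH1. It was above 0 for the others, up to 0.647 for URA3 and 0.738 for SRB4. Over the 9 bottle arrays ribosomal RNA signal rose with the 3' minus 5' difference, as fragmented RNA or short cDNA would give. The value of r was 0.736 (exact p = 0.0281), or 0.734 without the 2 farthest arrays, and rho was 0.65 (p = 0.0666). Adjusted p for r was 0.0422 over 3 relations, which include that of the ergosterol and seripauperin means given below, a separate question. The slope of level on coding length, 0.553 in the reference and 0.0275 in the bottles (exact p = 0.00455), gave little relation to the 3' minus 5' difference (r 0.0704, exact p = 0.859, rho 0.0833 with p = 0.843, r 0.214 without the 2 farthest). In ribosomal RNA signal the reference array without poly-A spike signal lay at -17% of the bottle gap from the other reference arrays. The length trend is excluded as the whole cause, since a median of 76.7% of the lower calls stayed after its removal. In poly-A spike signal every reference array lay outside the range of the bottle arrays, replicates 1 and 2 above it and replicate 3 below it. A difference in labelling or spiking was therefore not separated from any comparison with the reference. How far RNA quality or labelling lowered single genes against the reference stays open, because medium, growth phase and RNA quality changed together.

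Day 7 replicate 1 and day 19 replicate 1 stood apart from the other bottle arrays, and without them 314 genes were higher and 220 lower between day 19 and day 7. Both lay outside the other 7 in 1 of 4 quality measures, the poly-A spikes (7.74 for the lower of the pair, 7.672 for the highest other array), so array quality stays open. With their labels exchanged 2 genes were called, against 8 as given. That cannot exclude an exchange, since both arrays stay in the fit and the count moved widely with single arrays. Day 19 replicate 1 correlated at 0.832 with its own time and 0.861 with day 7, and day 7 replicate 1 at 0.892 with its own time and 0.862 with day 19. The higher value of day 7 replicate 1 with its own time gives no sign of an exchange, while a wrong label on day 19 replicate 1 alone stays open.

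For each comparison of 3 against 3 arrays the 10 splits are too few for a share under 0.05. Against the reference the real counts were 2007, 2447 and 2372, and the highest other split gave 0 each time (value 1 each). Day 15 against day 7 and day 19 against day 15 gave 0 genes against a highest other of 79 and 87, and day 19 against day 7 gave 8 against 10 (3 splits gave as many). For the F-test on the 9 bottle arrays the real value was 0 and the highest other 3, and with a real value of 0 all 100 splits give as many by construction, so that count tells nothing. With all 12 arrays chance is not excluded, with 2 genes against a highest other of 76 (18 of 100 splits gave as many). Whether the splits that called more genes than the real one reflect chance or a structure of the samples other than time was not tested. For genes called in one direction at all 3 times, the real count was 1486 and the highest other grouping gave 0. The other groupings mix reference and bottle arrays, so this shows only that reference and bottle arrays differ. It does not test the effect of the shared reference.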

How the results depend on the processing

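Counts are given as higher and lower genes, in the order day 7, day 15 and day 19 against the reference unless another is named; the cause was not tested. Array weights gave 1786 and 1697, 2115 and 2322 at days 7 and 15, 594 and 880 for day 15 against day 7, 514 and 290 for day 19 against day 15, 251 and 193 for day 19 against day 7, 1824 by the F-test, and 1310 and 1153 at all times. Adjusted p under 0.01 gave 633 and 414, 768 and 712, 751 and 560, 1 and 0 for day 19 against day 7, 0 by the F-test, and 488 and 265 at all times. A 2-fold minimum left 615 lower at day 7, 742 at day 19 and 398 at all times. For day 19 against day 7, median centring gave 2 lower, all probe sets 4 (and 1 for day 19 against day 15), trend and robust settings 3, removal of the length trend 2, and the 6 arrays alone 0 and 0. The F-test called 5 with median centring, 0 with quantile normalization, 4 without dim genes, 5 with all probe sets, 4 without shared sequence, 4 with trend and robust settings, 0 on the bottle arrays alone and 6 without the length trend. The replicate number as a fixed block gave 4 and 0 for day 19 against day 7 and 1 by the F-test, and as a random effect 4 by the F-test (consensus correlation 0.00676). The rule for pairing by number, all same-number pairs above 0.1, was not met. The 18 such pairs correlated from -0.277 to 0.414, 7 above 0.1, and 6 of 12 arrays correlated best with their own number. That cannot exclude pairing, since an array that stands apart shifts the deviations of its whole group. Without the pair of arrays apart, chosen after seeing the data, counts were 2 and 1 for day 15 against day 7, 173 and 88 for day 19 against day 15, 314 and 220 for day 19 against day 7 and 391 by the F-test. With single arrays left out, higher genes ranged from 736 to 1293, 858 to 1362 and 871 to 1320 and lower genes from 535 to 1176, 826 to 1487 and 711 to 1227. Day 15 against day 7 ranged from 0 to 27 higher and 0 to 80 lower, day 19 against day 15 from 0 to 33 and 0 to 16, day 19 against day 7 from 0 to 235 and 0 to 158, the F-test from 0 to 197, and genes at all times from 562 to 885 higher and 358 to 729 lower. Between bottle times the direction of some list tests, which compare a list with the other genes, changed when an array was left out; the medians of meiosis, beta-oxidation and glyoxylate genes stayed positive, and those of the other lists named here changed sign. For day 19 against day 7, nitrogen catabolite genes ranged from -0.17 to 0.0813 (highest without day 7 replicate 1) and ribosomal proteins from -0.25 to 0.0112 (highest without day 19 replicate 3). For day 15 against day 7, ribosomal proteins ranged from -0.13 to 0.0731 (highest without day 15 replicate 2). For day 19 against day 15 the ranges were -0.25 to 0.0585 for ribosomal proteins, 0.0544 to 0.46 for meiosis (where the value was 0.0544 without day 15 replicate 1), 0.032 to 0.65 for beta-oxidation (0.12 without day 15 replicate 1), 0.0587 to 1.28 for glyoxylate genes, -0.49 to 0.29 for ergosterol, -0.62 to 0.84 for seripauperin and -0.48 to 0.0582 for cell wall genes. Without the pair, nitrogen catabolite genes came to 0.35 for day 19 against day 7, and for day 19 against day 15 glyoxylate genes came to 0.0587, beta-oxidation 0.032, ergosterol 0.29, seripauperin 0.84, cell wall genes 0.0582 and DAN1 1.64. Against the reference 382 of 472 named gene calls held under all 27 alternatives, 0 of 75 list calls held under all 28, and 0 changed direction.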

Other observations

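Nutrient and cell surface genes add to the picture against the reference. Of the phosphate genes, 4 of 23 rose, 2 fell and 17 did not pass (3 and 1 adjusted over the list alone) at day 7 and 12 of 23 rose, 3 fell and 8 did not pass (13 and 4 adjusted over the list alone) at day 19 (list adjusted p = 0.443 and 0.106), with the transporter gene PHO84 at 3.49 ± 0.896 at day 19. In the zinc list, 2 of 15 rose, 5 fell and 8 did not pass (2 and 6 adjusted over the list alone) at day 7, with ZRT2, a zinc transporter gene, at -1.98 ± 0.31 (list adjusted p = 0.0727). Thiamine genes had 5 of 20 members that rose, 7 that fell and 8 that did not pass (5 and 8 adjusted over the list alone), with THI13 at 2.77 ± 0.433 and PET18 at -2.18 ± 0.343 (list adjusted p = 0.338), and the THI13 probe set shares sequence with other genes. Amino acid permeases had 3 of 22 members that rose, 3 that fell and 16 that did not pass (3 and 3 adjusted over the list alone), with AGP2 at 4.02 ± 0.363 (list adjusted p = 0.679), a median of -0.24 and a mean of 0.03. In the aroma list, 6 of 20 rose, 4 fell and 10 did not pass (7 and 5 adjusted over the list alone), with ADH7 at 3.96 ± 0.843 (list adjusted p = 0.447).

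Cell wall genes had 6 of 46 members that rose, 7 that fell and 33 that did not pass (6 and 7 adjusted over the list alone) at day 7, with PIR3, of the inner wall, at 3.89 ± 0.308 and GSC2, a glucan synthase subunit, at 2.76 ± 0.258 (list adjusted p = 0.927); the median was 0.01 and the mean -0.05. Drug efflux genes had 4 of 29 members that rose, 2 that fell and 23 that did not pass (4 and 2 adjusted over the list alone), with YGP1 at 2.70 ± 0.211 and the pump gene PDR5 at -1.88 ± 0.291 (list adjusted p = 0.679). Of the genes of the unfolded protein response, 3 of 30 fell and 27 did not pass (0 fell adjusted over the list alone) at day 7 (list adjusted p = 0.461) and 1 of 30 rose, 7 fell and 22 did not pass (0 and 6 adjusted over the list alone) at day 19 (list adjusted p = 0.219), with SEC61, of the translocation pore, at -1.19 ± 0.257.

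Seripauperin genes were higher at days 15 and 19 than at day 7 by 1.77 ± 0.484, and the test of shared sequence was chosen after the result was seen, as was the oxygen test within sampling times. Loss of oxygen in the sealed bottles may explain it: the ergosterol and seripauperin means moved together over the 9 bottle arrays (r 0.86, exact p = 0.00101, rho 0.917 with p = 0.00131, r 0.868 without the 2 farthest, adjusted p = 0.00303 over 3 relations), and with the means of each time removed r was 0.78 (p = 0.0185 over 216 permutations within times). Of 40 other lists 3 came as close or closer over the 9 arrays: the hypoxic list (r 0.906), and the zinc and mating lists, which the idea does not name (r 0.964 and 0.942). With the means of each time removed, 3 of the 40 other lists again came as close or closer. The relation is therefore not particular to the genes that the idea names. Respiratory chain genes showed little relation to the seripauperin mean (r -0.168), with medians of 0.06 and -0.14 for days 15 and 19 against day 7. That 1 array decides the difference is excluded (lowest value 1.56 with an array left out). Shared sequence stays open: the 3 members with probe sets of their own had medians of 2.12 and 1.44 for days 15 and 19 against day 7 (adjusted p = 0.00917 and 0.0454 by camera's preset test, and 0.704 and 0.51 for all 13 with an estimated correlation), but they are few, and the ergosterol genes and the TIR and DAN genes moved by 0.828 ± 0.48 and 1.60 ± 1.2, which lie within 2 standard errors of 0; oxygen was not measured, and measuring it in the bottles would test the idea.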
